A study of Mus musculus with 112 samples.

How the data were processed

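RNA from 112 skin and tumour samples of 15 mice was measured on Affymetrix whole-transcript arrays. The deposited values are log2 intensities of 28204 probe sets, made by the submitters with robust multi-array averaging (RMA) per their processing notes. The RMA version, and whether a batch correction was applied, are not given in the sources used here. No array values were missing. The values ran from 2.10 to 13.9 with a median of 6.12, and the medians of single arrays lay between 5.89 and 6.36. Any pair of arrays correlated between 0.833 and 0.993 across genes, and no pair shared more than 0.326% of identical values. The number of arrays limits the precision of every value.

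Probe sets were joined to gene symbols with the reference annotation. Of the probe sets, 21141 had 1 symbol, 1881 had several and 5182 were not named; the last 2 kinds were left out. For the 1367 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 18772 genes. No genome sequence or coordinates were used. Some genes were not analysed here.

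Several tumours came from 1 mouse, so the mouse was the replicate. The log2 values were averaged per mouse and group before testing. Arrays of a mixed histology were left out of the histology comparisons. All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and every p from limma is two-sided. Groups that came from the same mice were compared with mouse as a fixed block, and lung with lymph node metastases also with a histology covariate. Spindle and SCC tumours, and the difference in their change from carcinoma to metastasis, were compared with mouse as a random block through duplicateCorrelation over all genes. Genotypes were compared between mice with batch as a covariate, and the comparison of spindle with SCC metastases carried a genotype covariate. Batch 1 held 95 arrays of 13 mice and batch 2 held 17 arrays of 2 mice, 1 of each genotype. Adjusted p is Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The change per gene is given as a log2 difference with its SE, and group levels as the mean of mouse means with their SD.

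A total of 31 gene lists was fixed before the data were examined, as were the groups, the comparisons, the tests, most alternatives and the rule for named genes. The 13 pathway lists were cornified differentiation, hair follicle, epithelial adhesion, mesenchymal, hyperplastic epidermis, cell cycle, Ras-MAPK targets, Ras genes, interferon response, hypoxia and glycolysis, matrix proteases, Notch pathway and tumour suppressor loci. The 18 marker lists were skeletal muscle, adipocyte, sebocyte, fibroblast, endothelial, T cell, B cell, plasma cell, macrophage, neutrophil, mast cell, Langerhans cell, melanocyte, lung, liver, kidney, thymus and spleen or erythroid. Each list was tested against all other genes with cameraPR (two-sided) at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison, and again with the correlation estimated from the data. A list is described as higher or lower when its adjusted p at the preset correlation was under 0.05. Members were also tested with p adjusted over the list alone.

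Genes were named by a rule. It took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean log2 level of at least 6 in the higher group and, for fixed blocks, the same direction in every mouse. Predicted genes, microRNA genes, small nucleolar RNA genes and immunoglobulin or T-cell receptor segments were not named. It added 2 rising and 2 falling members of each list among those that passed, or the 2 members with the largest absolute change where none passed, and Nras. Lrrc56 was named by the rule in skin and elsewhere after its values had been seen.

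The similarity of tumours from 1 mouse was measured by centring every gene on the mean of its group and taking the mean Pearson correlation across genes of same-mouse pairs minus that of different-mouse pairs. Its one-sided p came from reassigning mice, by exact enumeration for 8 or fewer mice and otherwise from 100000 random reassignments, adjusted over the 4 pairs of groups. Genes are not independent replicates, and the mice were the units exchanged.

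The limma fits and the similarity test were tested on simulated data before use. At an added log2 change of 1, the fits recovered from 26% (HrasKO spindle metastasis) to 88% of changed genes. Up to 14 of 149 calls in a fit were false. The alternatives tried were individual arrays with mouse as a block, no mouse term, a fixed mouse block, the mean over probe sets, a filter on low values (above the overall median in at least 8 arrays), eBayes with trend and robust, quantile normalization repeated over all arrays, batch 1 alone, no batch or genotype covariate, both genotypes together, lymph node metastases alone, a shared histology, carcinomas titled RegCA left out, another gene set, centring or correlation for the similarity, and each mouse left out in turn. After the data had been seen, 4 were added: leaving out 12 arrays that stood apart, for limma and for the similarity, leaving out 6 papilloma arrays with a skeletal muscle mean above 6 between genotypes, and a mouse correlation from a smaller set of genes, which was tried first and set aside after its counts had been seen. An array stood apart by the class of its highest median correlation with arrays of other mice. This was spindle or normal skin for papilloma labels, spindle for SCC labels, or another class for spindle labels. The rule uses the tested values, so removing the arrays tends to widen class contrasts. Without an estimable mouse correlation the fit had no mouse term. For each limma count, up to 100 other mouse groupings were fitted.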

Results

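The samples came from a 2-stage skin carcinogenesis study of 15 male mice from a backcross of Mus spretus and FVB hybrids to FVB. The mice received the mutagen DMBA at 8 weeks of age and then repeated TPA, a tumour promoter. Primary tumours were resected when larger than 1 cm, and metastases were collected at sacrifice. Of the mice, 9 were wild type (WT) and 6 carried the knockout labelled HrasKO. The arrays covered 15 dorsal skins, 27 papillomas in 13 mice, 25 carcinomas and 45 metastases. By label, carcinomas were 10 squamous (SCC, 8 mice), 12 spindle (10 mice) and 3 mixed. Metastases were 24 SCC (11 mice), 20 spindle (7 mice) and 1 mixed. Metastases came from lymph node (24 arrays, 14 mice), lung (10 arrays, 10 mice), liver, spleen and thymus (3 arrays each), kidney (1 array) and a site labelled dorsal (1 array).

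The 10 carcinomas labelled SCC came from 8 of the 9 WT mice and 0 of the 6 HrasKO mice (Fisher's exact test, two-sided p = 0.0014). Mixed ones counted as not SCC, and HrasKO mice 1616 and 1706 had no others, that of 1706 lying closest to SCC arrays. The genotypes could thus be compared in spindle carcinomas alone. Of the 8 carcinomas titled RegCA, 7 were spindle, against 5 of the 17 others. Several share a mouse, so no test is given. RegCA is not defined in the sources used here. Histology and that title were thus partly bound together.

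**Figure D1:**
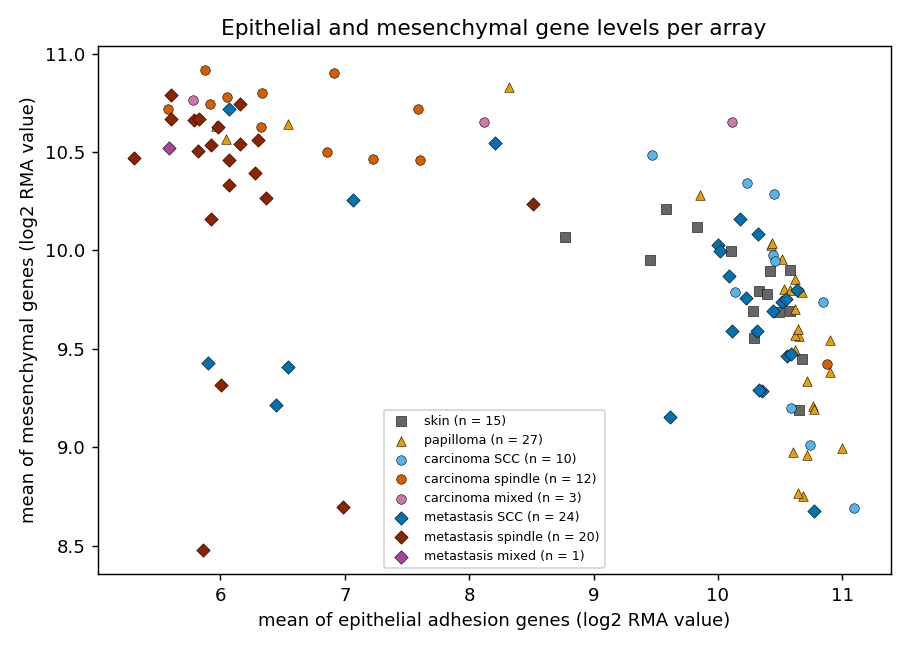
Mean log2 level of the epithelial adhesion list (horizontal axis) against that of the mesenchymal list (vertical axis), 1 point per array, with a colour and shape for each of 8 groups. Most spindle arrays lie at low epithelial values together with some papilloma and SCC metastasis arrays, and 1 spindle carcinoma array, from mouse 1949, lies among the papillomas at an epithelial mean of 10.9.

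Papillomas were compared with the skin of the same mice to describe the change from normal to benign tumour tissue. Papillomas had higher cell cycle transcripts and lower hair follicle, sebocyte, muscle and fat transcripts, although none of these lists held with an estimated correlation (adjusted p of at least 0.199). Sprr3, a cornified envelope precursor of internal epithelia, rose by log2 6.67 (SE 0.630) in 13 of 13 mice. Krt13, a keratin of internal stratified epithelia, rose from 5.02 ± 0.906 to 10.4 ± 2.08 (SD, n = 13). Pitx1, a homeobox transcription factor of the hindlimb and oral ectoderm, rose by 5.38 (SE 0.312), and Mmp13, a collagenase, by 4.05 (SE 0.408). The largest falls were those of Car3, a carbonic anhydrase of muscle and fat, which fell by 5.21 (SE 0.446), and of Krt77, a keratin of the upper epidermis, which fell by 5.09 (SE 0.335). Skint10 fell by 5.06 (SE 0.294), and Awat1, a wax ester enzyme of sebocytes, fell by 4.09 (SE 0.441). The remaining genes with the largest rises were Lce3f, Bpifa5, Tmprss11b and Lce3b, and those with the largest falls were Ces1d, Sectm1b, Mc5r and Cidec.

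All 20 measured cell cycle genes rose in papillomas, among them Cdc20 (log2 1.99, SE 0.186) and the mitotic kinase Aurka (1.89, SE 0.189). The list had a median change of 1.48 (adjusted p = 3.02e-12, and adjusted p = 0.301 with an estimated correlation). Of the 19 Ras-MAPK targets, 12 rose and 1 fell (median 1.19, adjusted p = 0.000164, and adjusted p = 0.577 with an estimated correlation). They included Hmga2, a chromatin protein of embryonic tissue, at 3.14 (SE 0.330) and Hbegf, a ligand of the EGF receptor, at 2.57 (SE 0.317). In the hyperplastic epidermis list, 11 of 16 genes rose, with Serpinb3a at 3.31 and the defensin Defb3 at 3.27 (adjusted p = 0.0055, and adjusted p = 0.702 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 14 cases, 11 when adjusted over the list alone, with Hk2 at 1.46 and the glucose transporter Slc2a1 at 1.18 (adjusted p = 9.01e-05, and adjusted p = 0.301 with an estimated correlation). Among 12 matrix proteases, 7 rose and 2 fell, with Mmp9 at 3.60 (adjusted p = 0.0231, and adjusted p = 0.702 with an estimated correlation). Counts adjusted over the list alone were equal to those over all genes in this comparison unless given.

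Of the lists that were lower in papillomas, sebocyte markers fell in 9 of 10 cases, with a median of -3.14 (adjusted p = 3.13e-09, and adjusted p = 0.199 with an estimated correlation). All 14 skeletal muscle genes fell, with Atp2a1 at -4.05 and Myl1 at -3.84, each lower in 11 of 13 mice (adjusted p = 0.702 with an estimated correlation). Hair follicle genes fell in 15 of 17 cases, 16 when adjusted over the list alone, with the hair keratins Krt31 at -3.36 and Krt33a at -3.32 (adjusted p = 0.702 with an estimated correlation). Adipocyte genes fell in 7 of 9 cases, with Plin4 at -3.50 (adjusted p = 0.301 with an estimated correlation). Smaller falls were shared by 5 of 11 fibroblast, 6 of 9 endothelial and 5 of 7 mast cell markers, where 1 was also higher when adjusted over the list alone (adjusted p = 0.702 with an estimated correlation for each). Cornified differentiation was lower with a median of -0.56, 2 genes fallen and 1 risen, 2 and 0 when adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.778 with an estimated correlation). That median was 0.15 and not called without the 5 papilloma arrays that stood apart, of which 4 lay closest to spindle tumours and 1 to normal skin. Matrix protease (adjusted p = 0.143) and mast cell lists (adjusted p = 0.0682) lost their call as well without them.

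The other lists were not called between papilloma and skin. Neutrophil markers rose in 5 of 7 cases and fell in 1 (median 1.40, adjusted p = 0.069), with Trem1 at 3.21 and Retnlg at 2.65. T cell markers fell in 3 of 8 cases and rose in 1, with Cd3g, a T cell receptor subunit, at -2.00. Tumour suppressor loci rose in 2 of 7 cases, with Cdkn2a, a cell cycle inhibitor, at 1.82 (SE 0.234), and fell in 3, with Rb1 at -0.63. Epithelial adhesion genes rose in 2 and fell in 2 of 24 cases, and mesenchymal genes rose in 1 and fell in 5 of 19. When adjusted over the list alone, 2 adhesion genes were higher and 1 lower, and 2 mesenchymal genes were lower. Notch pathway genes rose in 4 and fell in 1 of 9 cases, and interferon response genes rose in 1 and fell in 1 of 14, with none when adjusted over the list alone. Of the 4 Ras genes, Rras fell by 0.47 (SE 0.151), and Nras, a Ras GTPase, had a change of 0.09 (adjusted p = 0.296). Langerhans cell markers fell in 2 of 6 cases, liver markers in 2 of 11, and melanocyte (6), lung (11) and thymus (6) markers in 1 case each, 0 for melanocyte when adjusted over the list alone. B cell (9), plasma cell (5), macrophage (10), kidney (7) and spleen or erythroid (4) markers rose in 1 case each. By limma, 4593 genes were higher and 3400 lower in papillomas, of which 689 and 986 changed more than 2-fold.

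SCC carcinomas were compared with papillomas of the same 8 mice, the step from benign to malignant squamous tumour. Matrix protease and neutrophil genes were higher and melanocyte genes lower, and few single genes passed the test. The largest falls were those of Rnase2b, a ribonuclease of the eosinophil-associated family, which fell by 3.65 (SE 0.334, adjusted p = 0.0106), and Oas1f, a member of an interferon-induced enzyme family, which fell by 2.98 (SE 0.291). Cyp2b19, a keratinocyte cytochrome, fell by 2.71 (SE 0.257), and Adh7, a retinol dehydrogenase, fell by 2.54 (SE 0.323). Aox4, Serpina12, Orm1 and Pou2f3, a transcription factor of keratinocyte differentiation, fell as well (-2.53 to -1.92). The 2 genes that rose were Prl2c5, at 2.31 (SE 0.347, adjusted p = 0.0456), and Apobr, at 1.09 (SE 0.163, adjusted p = 0.0456).

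No list member passed over all genes in this comparison. Of 12 matrix proteases, 6 were higher when adjusted over the list alone (median 0.62, adjusted p = 4.09e-07, and adjusted p = 0.000633 with an estimated correlation), with Mmp3 at 1.70 and Mmp12 at 1.44. Of 7 neutrophil markers, 5 were higher when adjusted over the list alone (median 0.61, adjusted p = 0.00363 with an estimated correlation). Of 6 melanocyte markers, 5 were lower when adjusted over the list alone (median -0.89, adjusted p = 0.0336 with an estimated correlation), with the pigment enzymes Dct at -2.06 and Tyrp1 at -2.30. Cornified differentiation had a median of -1.30 and 6 of 14 genes lower when adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). Krt1, a keratin of differentiating epidermis, had a change of -2.71 (adjusted p = 0.116). Lists lost with an estimated correlation were also Ras-MAPK targets (median 0.29, adjusted p = 0.38 with an estimated correlation) and cell cycle (0.14, adjusted p = 0.839 with an estimated correlation). Skeletal muscle (0.39, adjusted p = 0.781), sebocyte (-0.64, adjusted p = 0.375) and mast cell (-0.57, adjusted p = 0.441) were lost as well with an estimated correlation.

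By limma, 2 genes were higher and 36 lower in SCC carcinomas. The count was 0 in batch 1 alone or without mouse 1383, 1456 or 2022, and 377 (81 higher, 296 lower) without the arrays that stood apart, where all 38 genes were again called.

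Spindle carcinomas were compared with papillomas of the same 9 mice. They had lost most epithelial adhesion, envelope and epidermal hyperplasia transcripts and gained mesenchymal, macrophage and Ras pathway transcripts, although none of these lists held with an estimated correlation (adjusted p of at least 0.269). The cornified envelope genes Lce1f and Lor fell by 5.33 (SE 0.602) and 4.31 (SE 0.637). Bpifa5 fell by 5.26 (SE 0.709), Dsg3, a desmosomal cadherin, fell by 4.33 (SE 0.882), and Esrp1, an epithelial splicing regulator, fell by 3.93 (SE 0.756). Rptn, Dsg1b, Lce1c, Serpinb3a and Aadacl2 fell as well (-4.88 to -4.21). Camk1g, a calmodulin-dependent kinase, rose by 3.36 (SE 0.641), the sodium-proton exchanger Slc9a2 by 2.65 (SE 0.419), and the chemokine Cx3cl1 by 1.81 (SE 0.244). Hmga2 rose by 1.77 (SE 0.343), with Arhgap22, Unc13c, Krt18 and Sema7a between 1.78 and 2.26.

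All 14 cornified differentiation genes fell (median -3.78, adjusted p = 2.98e-14, and adjusted p = 0.269 with an estimated correlation). Epithelial adhesion genes fell in 22 of 24 cases, 23 when adjusted over the list alone (median -2.78, adjusted p = 0.357 with an estimated correlation). In the hyperplastic epidermis list, 13 of 16 genes fell, with Defb3 at -4.74, and 2 rose, with the simple epithelial keratin Krt8 at 2.50, 14 and 2 when adjusted over the list alone (adjusted p = 0.357 with an estimated correlation). Mesenchymal genes rose in 10 of 19 cases, 15 when adjusted over the list alone (adjusted p = 0.63 with an estimated correlation). Among them the transcription factor Snai1 rose by 1.75 (SE 0.349), whereas its relative Snai2 fell by 0.73 (SE 0.148). Of the Ras genes, Mras rose by 1.78 (SE 0.349) and Rras by 0.80, and 3 of 4 were higher when adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). The change of Nras was 0.14 (adjusted p = 0.161).

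Ras-MAPK targets rose in 10 of 19 cases, with Spry4, a feedback inhibitor, at 1.82, and 11 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Macrophage markers rose in 5 of 10 cases, 9 when adjusted over the list alone, with the complement genes C1qa at 1.43 and C1qc at 1.45 (adjusted p = 0.63 with an estimated correlation). Cell cycle genes rose in 6 of 20 cases, 13 when adjusted over the list alone (adjusted p = 0.706 with an estimated correlation). Notch pathway genes fell in 6 of 9 cases, with Notch3 at -1.78 and its ligand Jag2 at -1.67 (7 lower and 1 higher when adjusted over the list alone), and all 6 melanocyte markers fell (adjusted p = 0.357 with an estimated correlation for each). Adipocyte markers fell in 3 and sebocyte markers in 2 cases (adjusted p = 0.59 with an estimated correlation for each). T cell markers fell in 3 of 8 cases (adjusted p = 0.63 with an estimated correlation), and hair follicle genes in 1 of 17 (adjusted p = 0.834 with an estimated correlation). In uncalled lists, the growth factor receptor Pdgfra rose by 1.98, Plau by 1.14, Nf1 by 0.85, P4ha1 by 0.81, Smad4 by 0.51, Mfge8 by 0.50 and Fkbp11 by 0.36. In those lists Slc34a2 fell by 3.74, Epcam by 2.40, Egln3 by 1.32, Hk2 by 1.21, Cd207 by 1.11, Cdkn1a by 0.57 and Scgb3a2 by 0.36.

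By limma, 2369 genes were higher and 2101 lower in spindle carcinomas. The count was 0 when RegCA carcinomas were left out, 2278 in batch 1 alone (934 higher, 1344 lower) and 7912 without the arrays that stood apart. Without those arrays the calls of Ras-MAPK targets (adjusted p = 0.135), cell cycle (0.151), adipocyte (median 0.03, adjusted p = 0.297), T cell (0.641) and hair follicle lists (0.247) ended. Leaving out 1 mouse gave counts from 2105 to 5785.

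Spindle and SCC carcinomas of WT mice were compared with each other (6 and 8 mice, 5 with both). Spindle carcinomas had lower cornified differentiation and hyperplastic epidermis transcripts. Epithelial adhesion transcripts were lower as well (adjusted p = 0.0651 with an estimated correlation). Dsg3 was 6.70 ± 3.12 (SD, n = 6) in spindle and 11.6 ± 0.420 (SD, n = 8) in SCC carcinomas. The defensin Defb4 fell by 5.34 (SE 0.892), Sprr2e by 4.91 (SE 0.733) and Esrp1 by 4.28. The kallikreins Klk14 and Klk9 and the genes Tmem45b, Lce3f and Lce3a fell as well (-4.79 to -4.74). The axon guidance gene Ntn1 rose by 3.32 (SE 0.738), the nuclear receptor Nr2f1 by 3.29 (SE 0.751) and the matrix protein Mgp by 2.92 (SE 0.708). Gpr149 rose by 3.37 (SE 0.919), and Ogn, Osr1, Adamtsl3 and Sema3a rose by 2.87 to 3.04.

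Cornified differentiation fell in 8 of 14 cases, 10 when adjusted over the list alone (median -3.36, adjusted p = 1.5e-11, and adjusted p = 0.0456 with an estimated correlation). Hyperplastic epidermis genes fell in 11 of 16 cases, 14 when adjusted over the list alone, with Krt16 at -4.68 (median -3.56, adjusted p = 0.0312 with an estimated correlation). Epithelial adhesion genes fell in 21 of 24 cases, 23 when adjusted over the list alone (median -3.29, adjusted p = 1.92e-25, and adjusted p = 0.0651 with an estimated correlation). Of 19 mesenchymal genes, Zeb1 rose by 1.70 (SE 0.470), Snai1 rose by 1.49 (SE 0.343) and Snai2 fell by 1.11 (SE 0.295), and 12 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Notch pathway genes fell in 4 of 9 cases, with Dll1 at -1.92 and Nrarp at -2.08, and Notch2 rose by 0.46, 7 lower and 1 higher when adjusted over the list alone (adjusted p = 0.193 with an estimated correlation). The antiviral genes Ifit2 and Ifit3 rose by 1.62 and 1.97, 3 interferon genes being higher when adjusted over the list alone (adjusted p = 0.454 with an estimated correlation). Of 10 macrophage markers, Itgam rose by 0.83, and 7 were higher when adjusted over the list alone (adjusted p = 0.675 with an estimated correlation). Adipocyte markers fell in 2 of 9 cases, 3 when adjusted over the list alone (adjusted p = 0.215 with an estimated correlation), and sebocyte markers in 2 of 10 (adjusted p = 0.694 with an estimated correlation). Hair follicle (adjusted p = 0.709) and hypoxia genes (adjusted p = 0.738) fell in 1 case each and were also lost with an estimated correlation. In uncalled lists, Mras rose by 1.92, Mfge8 by 0.80, Rras by 0.70, the cyclin Ccnd1 by 0.47 and Smad4 by 0.44, and Slc34a2 fell by 3.16, Epcam by 2.83, Mmp13 by 2.37 and Cdkn1a by 0.61. For Nras the change was 0.05 (adjusted p = 0.853).

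By limma, 652 genes were higher and 767 lower in spindle carcinomas. The count fell to 0 with a fixed mouse block and to 1 without mouse 1984, and reached 3679 (2062 higher, 1617 lower) without the arrays that stood apart and 4056 without mouse 1949, whose spindle carcinoma array lay closest to papillomas. It was 657 in batch 1 alone, 2140 with individual arrays (1079 higher, 1061 lower), 1785 after a repeated quantile normalization (938 and 847) and 4297 with mice of both genotypes (2580 and 1717).

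SCC metastases were compared with SCC carcinomas of the same 8 mice. Metastases had lost cornified envelope, hyperplastic epidermis and matrix protease transcripts and gained B cell and plasma cell transcripts. Lce1c fell by 4.66 (SE 0.516), Lce3f by 4.81 (SE 0.864) and Alox12b, a lipoxygenase of the skin barrier, by 4.46 (SE 0.680). Defb4, Rptn, Sdr9c7, Lce3a and Lce1h fell as well (-4.66 to -4.45). Cd79a, a subunit of the B cell receptor, rose from 5.0 ± 0.135 to 8.34 ± 1.29 (SD, n = 8). Cd79b rose by 2.95 (SE 0.400), Jchain, the joining chain of polymeric antibodies, by 3.74 (SE 0.624), and Mzb1 by 3.74 (SE 0.645). Lgr6, a receptor of skin stem cells, rose by 2.87 (SE 0.609), and Pou2af1, Ms4a1 and Alox15 by 2.78 to 2.87.

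Of 9 B cell markers, 3 rose, and 8 were higher when adjusted over the list alone (median 1.25, adjusted p = 4.28e-10, and adjusted p = 0.0264 with an estimated correlation). Plasma cell markers rose in 3 of 5 cases, 4 when adjusted over the list alone (median 2.61, adjusted p = 0.0473 with an estimated correlation). Cornified differentiation fell in 9 of 14 cases, 12 when adjusted over the list alone, with Krt1 at -4.36 and Tgm3 at -4.35 (median -3.51, adjusted p = 9.14e-22, and adjusted p = 0.00227 with an estimated correlation). Hyperplastic epidermis genes fell in 5 of 16 cases, and 2 were higher and 10 lower when adjusted over the list alone (median -1.43, adjusted p = 0.0264 with an estimated correlation). Matrix proteases fell in 3 of 12 cases, 4 when adjusted over the list alone, with the stromelysins Mmp3 at -3.54 (SE 0.285) and Mmp10 at -2.97 (SE 0.299) (median -0.32, adjusted p = 0.00609 with an estimated correlation). Interferon response genes rose in 3 of 14 cases, 7 when adjusted over the list alone, with Irf7 at 1.42 and Gbp3 at 1.16 (adjusted p = 0.14 with an estimated correlation). Of 8 T cell markers, Cd3d rose by 1.11, and 6 were higher when adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). The macrophage markers C1qa and C1qc rose by 1.42 and 1.33, 3 of 10 markers being higher when adjusted over the list alone (adjusted p = 0.402 with an estimated correlation). The lung marker Napsa rose by 1.11 (adjusted p = 0.604 with an estimated correlation). Epithelial adhesion had a median of -0.80 with 1 gene fallen (adjusted p = 0.694 with an estimated correlation). Cell cycle had a median of -0.32 with 0 genes past the threshold of limma (adjusted p = 0.733 with an estimated correlation). Hair follicle (-0.84, adjusted p = 0.57) and sebocyte lists (-0.66, adjusted p = 0.402) were also lost with an estimated correlation, each with 1 gene fallen. The Nras transcript had a change of -0.00 (adjusted p = 0.998).

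By limma, 339 genes were higher and 515 lower in SCC metastases. The count was 60 with lymph node metastases alone, 202 in batch 1 alone or without mouse 1456, 2462 with individual arrays and 459 without the arrays that stood apart.

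In the 7 mice with both, spindle metastases and spindle carcinomas were compared in the same way. No gene passed by limma, with 2495 genes at an unadjusted p under 0.05, and lists differed as groups. The largest differences in lymphoid markers were Jchain at 3.70 (adjusted p = 0.255), Mzb1 at 3.55 (adjusted p = 0.267) and Ms4a1 at 3.20 (adjusted p = 0.279). Keratins had Krt14 at -3.59 (adjusted p = 0.267) and Krt6b at -3.94 (adjusted p = 0.3). Nras had a change of -0.21 (adjusted p = 0.389).

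Interferon response genes were higher in spindle metastases, with 2 of 14 past the threshold when adjusted over the list alone (median 0.56, adjusted p = 6.7e-08, and adjusted p = 0.0379 with an estimated correlation). Adipocyte markers were higher in 6 of 9 cases when adjusted over the list alone (median 0.84, adjusted p = 0.0379 with an estimated correlation), a call lost with individual arrays (adjusted p = 0.0882). T cell markers were higher in 8 of 8 cases when adjusted over the list alone (median 1.39, adjusted p = 0.143 with an estimated correlation). B cell markers were higher in 7 of 9 cases when adjusted over the list alone (median 1.59, adjusted p = 0.136 with an estimated correlation). Plasma cell (median 2.47) and spleen or erythroid markers (0.58) were higher in 3 cases each when adjusted over the list alone (adjusted p = 0.102 with an estimated correlation for each). Skeletal muscle genes were lower in 12 of 14 cases when adjusted over the list alone (median -0.94), as was 1 of 14 cornified differentiation genes (median -1.19) (adjusted p = 0.136 with an estimated correlation for each). Hair follicle (-0.35), epithelial adhesion (-0.75), hyperplastic epidermis (-0.82), hypoxia (-0.40) and matrix protease lists (-0.45) were lower, and lung (0.81) and liver lists (0.36) higher (adjusted p = 0.423 with an estimated correlation for each). Mesenchymal (-0.22, adjusted p = 0.658), Ras-MAPK (-0.53, adjusted p = 0.403) and Notch lists (-0.51, adjusted p = 0.383) were lower and also lost with an estimated correlation. In these last 10 lists, at most 2 genes passed when adjusted over the list alone. With lymph node metastases alone the mesenchymal and liver medians turned to 0.14 and -0.05. The gene count was 22 with individual arrays.

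Whether the change from carcinoma to metastasis differed between spindle and SCC histology was tested directly (7 and 8 mice). No gene passed by limma, with 1706 genes at an unadjusted p under 0.05. The largest differences were in epidermal genes, with Defb3 at 3.88 (SE 0.612, adjusted p = 0.126) and Casp14, a protease of the cornified layer, at 3.37 (SE 0.570, adjusted p = 0.126). The change of Nras was -0.20 (adjusted p = 0.679). Cornified differentiation had a median difference of 1.80, with 4 genes higher when adjusted over the list alone (adjusted p = 0.382 with an estimated correlation). The count was 98 with individual arrays, 19 without RegCA carcinomas, 11 without mouse 2022 and 3 without both the arrays that stood apart and a mouse term.

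Spindle and SCC metastases were compared across both genotypes (7 and 11 mice, 3 with both). Spindle metastases had lower Notch pathway transcripts as a group, and epithelial adhesion transcripts were lower as well (adjusted p = 0.0578 with an estimated correlation). Mpzl2, an epithelial adhesion molecule, was 5.65 ± 0.818 (SD, n = 7) in spindle and 9.65 ± 1.63 (SD, n = 11) in SCC metastases. The receptor phosphatase Ptprf fell by 3.02 (SE 0.522), the laminin receptor Bcam by 2.66 (SE 0.422), the adhesion molecule Chl1 by 1.46 (SE 0.250) and Ahcyl2 by 0.83 (SE 0.138), each with an adjusted p of 0.0461. Cpne7 rose by 1.12 (SE 0.194), the mitotic gene Depdc1a by 1.03 (SE 0.173) and Abhd8 by 0.73 (SE 0.131), and Rnf26, Ncln, Ptpa, Wdr83os and Tor1b rose by 0.34 to 0.56. For Nras the change was 0.04 (adjusted p = 0.85).

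No list member passed over all genes. Notch pathway genes were lower in 7 of 9 cases when adjusted over the list alone (median -0.95, adjusted p = 2.28e-07, and adjusted p = 0.0247 with an estimated correlation). Epithelial adhesion genes were lower in 23 of 24 cases when adjusted over the list alone (median -2.59, adjusted p = 6.75e-28, and adjusted p = 0.0578 with an estimated correlation), with Dsg3 at -3.92 and Epcam at -2.93. Hyperplastic epidermis genes were lower in 9 cases when adjusted over the list alone (median -1.81, adjusted p = 0.103 with an estimated correlation), with Krt6b at -4.64. Cell cycle genes were higher in 15 of 20 cases when adjusted over the list alone (median 0.58, adjusted p = 0.299 with an estimated correlation), with Ccnb2 at 0.70. Langerhans cell markers had a median of -0.31 (adjusted p = 0.222 with an estimated correlation). Cornified differentiation (-0.27, 3 genes lower when adjusted over the list alone) and endothelial lists (-0.60, 1 gene) were lower (adjusted p = 0.536 with an estimated correlation for each). Hypoxia (-0.41), neutrophil (-0.90) and lung lists (-1.54) were lower (adjusted p = 0.47 with an estimated correlation for each), and the mesenchymal list was higher (0.34, adjusted p = 0.771 with an estimated correlation).

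By limma, 8 genes were higher and 5 lower in spindle metastases. The count was 0 with no mouse block, a fixed mouse block, a trended and robust variance or batch 1 alone, and 611 without the genotype covariate. It was 1951 with individual arrays and 1484 (657 higher, 827 lower) without the arrays that stood apart, in a fit that also had no mouse term.

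Lung and lymph node metastases of the same 8 mice were compared to separate the host organ from the tumour. Lung markers were higher in lung metastases, and no single gene passed by limma, with 1155 genes at an unadjusted p under 0.05. Sftpc, a surfactant protein, was 10.9 ± 2.46 in lung and 4.05 ± 0.201 in lymph node metastases (SD, n = 8), higher in 8 of 8 mice (adjusted p = 0.181). Scgb1a1, a secretory protein of airway cells, had a change of 7.01 (SE 0.937, adjusted p = 0.181). All 11 lung markers were higher when adjusted over the list alone (median 4.95, adjusted p = 1.2e-63, and adjusted p = 2.28e-08 with an estimated correlation). Interferon response genes were higher in 2 cases when adjusted over the list alone (median 1.00), and matrix protease (-0.67, 1 gene lower when adjusted over the list alone) and fibroblast lists (-1.04) were lower (adjusted p = 0.202 with an estimated correlation for each). Endothelial (0.80) and B cell lists (1.13) were higher and mesenchymal (-0.30), adipocyte (-1.65) and macrophage lists (-0.62) lower (adjusted p = 0.648 with an estimated correlation for each). T cell markers (0.75) were higher and skeletal muscle genes (-1.02) lower (adjusted p = 0.651 with an estimated correlation for each). Langerhans cell markers were higher (0.67, adjusted p = 0.289 with an estimated correlation) and Ras-MAPK targets lower (-0.34, adjusted p = 0.711 with an estimated correlation). The Nras transcript had a change of -0.17 (adjusted p = 0.964). The alternatives gave counts of up to 83, with individual arrays.

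**Figure D2:**
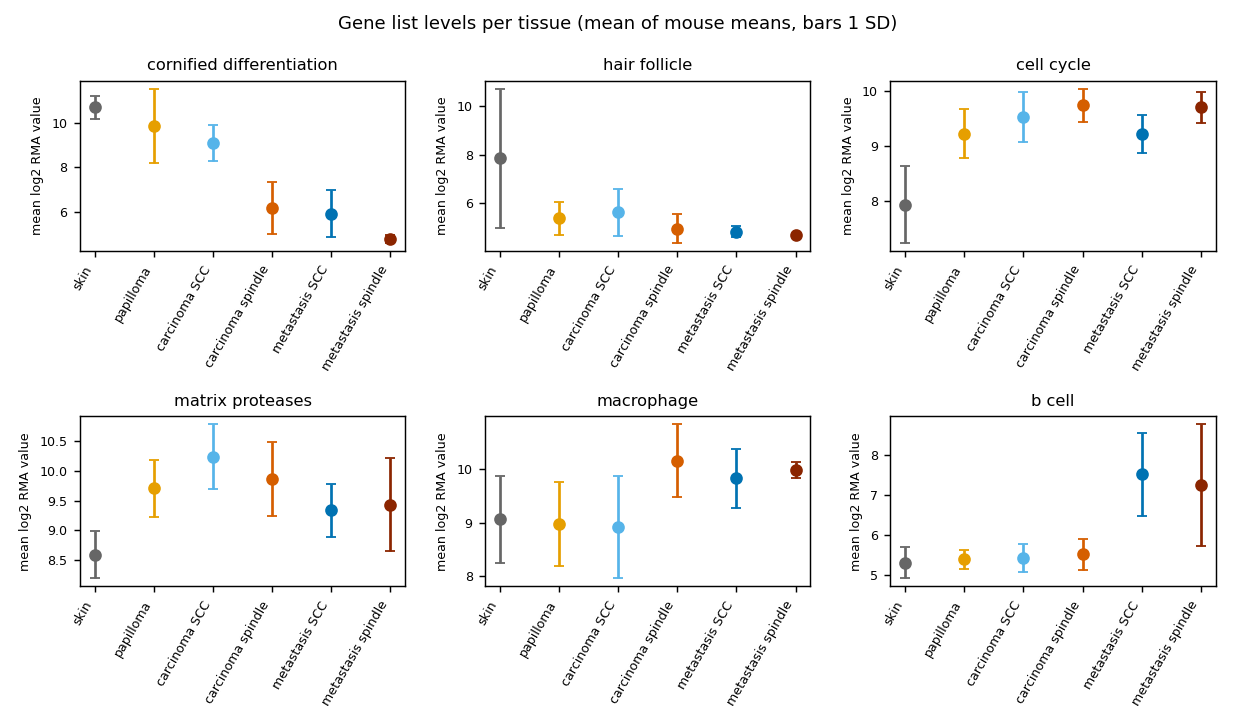
Mean log2 level of 6 gene lists in 6 tissue groups, as the mean over mice with bars of 1 SD, in 1 panel per list. Cornified differentiation genes lie at 9.10 in SCC carcinomas, 6.17 in spindle carcinomas, 5.91 in SCC metastases and 4.77 in spindle metastases.

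The genotypes were compared within each tissue to ask what the HrasKO allele changed. In skin, 1 gene differed by limma. Lrrc56, a leucine-rich repeat gene, was 6.66 ± 0.141 (SD, n = 6) in HrasKO and 5.88 ± 0.223 (SD, n = 9) in WT skin, a rise of 0.80 (SE 0.0920, adjusted p = 0.00896). Its call was lost in batch 1 alone and without mouse 1456, 1509, 1616 or 1664, with a change of 0.75 to 0.83 and an adjusted p of at most 0.0606 over all alternatives. Skeletal muscle (median 1.94) and B cell lists (0.17), each with 1 gene higher when adjusted over the list alone, and the adipocyte list (1.71) were higher (adjusted p = 0.82 with an estimated correlation for each). The fibroblast list (0.45) was higher and the epithelial adhesion (-0.30) and Ras-MAPK lists (-0.31) lower (adjusted p = 0.826 with an estimated correlation for each). Nras had a change of -0.19 (adjusted p = 0.533).

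**Figure D3:**
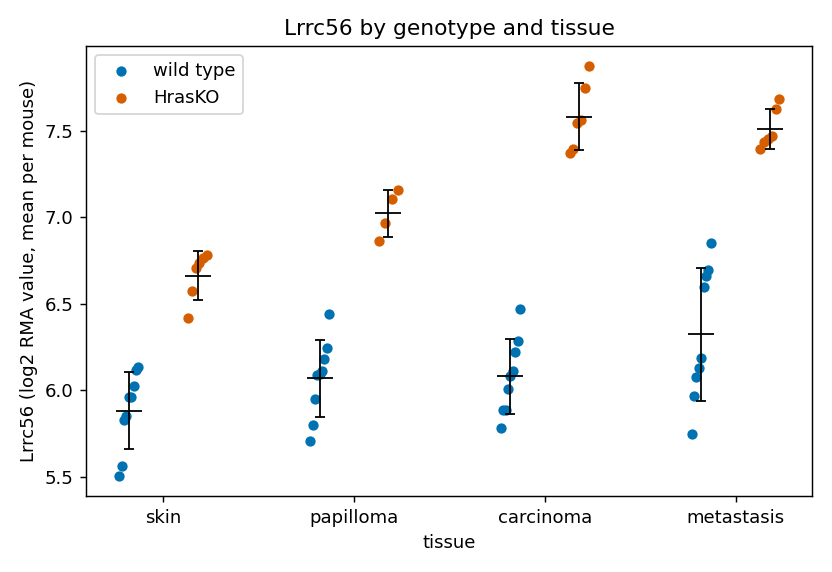
Log2 level of Lrrc56 in skin, papilloma, carcinoma and metastasis, 1 point per mouse, with the mean and bars of 1 SD for HrasKO and WT mice. The genotypes do not overlap in any of the 4 tissues, with means of 7.58 and 6.08 in carcinomas.

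The HrasKO papillomas had lower Ras-MAPK target transcripts than WT papillomas (4 and 9 mice), and lower cell cycle transcripts that depended on arrays with muscle transcripts. Of 20 cell cycle genes, 18 were lower when adjusted over the list alone (median -0.64, adjusted p = 1.35e-33, and adjusted p = 0.00979 with an estimated correlation). The mitotic genes Cdc20 and Plk1 were at -0.92 (SE 0.199, adjusted p = 0.581) and -0.97 (SE 0.221, adjusted p = 0.599). Of 19 Ras-MAPK targets, 3 were lower when adjusted over the list alone (median -0.51, adjusted p = 5.12e-12, and adjusted p = 0.00979 with an estimated correlation). Among them were Dusp6, a phosphatase that dampens MAP kinase signalling, at -0.97 (SE 0.266, adjusted p = 0.635), and Hbegf at -0.98 (adjusted p = 0.832). Both lists kept their direction and their call at the preset correlation in 22 of 22 alternatives, with medians from -0.86 to -0.23 for cell cycle and from -0.65 to -0.29 for Ras-MAPK targets. The smallest cell cycle median came without the 6 papilloma arrays that had a skeletal muscle mean above 6 (2 of the 8 HrasKO and 4 of the 19 WT arrays), a choice made after the levels had been seen. Of these arrays, the 2 from HrasKO mice had cell cycle means of 7.69 and 7.96 with muscle means of 10.5 and 10.6, and the 4 from WT mice had cell cycle means of at least 9.07. Without them the cell cycle list was lost (adjusted p = 0.694 with an estimated correlation), whereas Ras-MAPK targets held (median -0.37, adjusted p = 0.000934 with an estimated correlation). By limma, 1 gene passed, Bub3, a protein of the spindle checkpoint, at 9.06 ± 0.0270 (SD, n = 4) in HrasKO and 9.58 ± 0.0610 (SD, n = 9) in WT papillomas (adjusted p = 0.0188). Bub3 passed in 8 of its 22 alternatives and was lost in batch 1 alone, with a filter on low values, with individual arrays, without the arrays that stood apart, without those with muscle transcripts and without each of 9 mice. The count was 33 without mouse 1509. Lrrc56 had a change of 0.95 (adjusted p = 0.0825), or 1.07 (adjusted p = 0.0149) without the arrays with muscle transcripts, and Nras of -0.02 (adjusted p = 1).

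Other lists that differed in papillomas were lost with an estimated correlation. Cornified differentiation (0.84), epithelial adhesion (0.55) and interferon response (0.31) were higher in HrasKO papillomas (adjusted p = 0.879 with an estimated correlation for each). The first pair turned to -0.12 and -0.04 without the arrays that stood apart. Skeletal muscle (1.06, adjusted p = 0.567), T cell (0.28, adjusted p = 0.339), Langerhans cell (0.25, adjusted p = 0.459) and melanocyte lists (0.86, adjusted p = 0.53) were also higher and also lost with an estimated correlation. Without the arrays with muscle transcripts the skeletal muscle median was 0.07 and not called.

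Whether papilloma formation changed genes differently in the genotypes was tested as a difference of changes from skin (4 and 9 mice). No gene passed by limma, with 1419 genes at an unadjusted p under 0.05, and 34 passed with individual arrays. In the cell cycle list, the change of HrasKO mice lay below that of WT mice (median difference -0.54, adjusted p = 0.0163, and adjusted p = 0.792 with an estimated correlation), and the difference was -0.08 and not called without the arrays with muscle transcripts. The Ras-MAPK list was not called (median difference -0.14, adjusted p = 0.574). Phlda1 had a difference of -1.12 (adjusted p = 0.599) and Nras of 0.29 (adjusted p = 0.646).

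In spindle carcinomas (4 HrasKO and 6 WT mice), no gene differed by limma, with 626 genes at an unadjusted p under 0.05. Lrrc56 had a change of 1.23 (adjusted p = 0.991), the cadherin Cdh11 of 1.04 (adjusted p = 0.991), Irf7 of -1.75 (adjusted p = 0.991) and Nras of 0.26 (adjusted p = 0.991). Cell cycle genes (0.34), interferon response genes (-0.71), sebocyte (0.77), B cell (-0.49) and neutrophil markers (-0.83) differed as lists (adjusted p = 0.548 with an estimated correlation for each). Hair follicle (0.45) and hyperplastic epidermis genes (-1.09) differed as well (adjusted p = 0.607 with an estimated correlation for each). So did Ras-MAPK (0.29, adjusted p = 0.33), epithelial (-0.70, adjusted p = 0.77), mesenchymal (0.22, adjusted p = 0.752) and endothelial lists (-0.43, adjusted p = 0.629), each p with an estimated correlation. Of these 11 lists, 1 mesenchymal and 1 sebocyte gene passed when adjusted over the list alone. The hair follicle median was -0.01 without RegCA carcinomas.

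Against 8 WT mice, SCC metastases of 3 HrasKO mice had lower Ras-MAPK target and higher interferon response transcripts. Both turned without the arrays that stood apart. Tfap2a, a transcription factor of epidermis, was 7.32 ± 0.646 (SD, n = 3) in HrasKO and 9.94 ± 0.288 (SD, n = 8) in WT metastases. Moxd1 fell by 3.46 (SE 0.471, adjusted p = 0.0346), and Pitx1 by 3.19 (SE 0.435). The ephrin receptor Epha2 and the genes Anxa8, Stra6, Lratd1 and Serinc2 fell as well (-2.63 to -2.29). Hes1, a Notch target, fell by 1.30 (SE 0.201, adjusted p = 0.0475). The antiviral gene Ifit1 rose by 1.93 (SE 0.254, adjusted p = 0.0346), Cadm3 by 1.43 and Strip2 by 1.12. Lrrc56 had a change of 1.04 (adjusted p = 0.153) and Nras of -0.15 (adjusted p = 0.666).

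Of 19 Ras-MAPK targets, 5 were lower when adjusted over the list alone (median -0.62, adjusted p = 2.53e-09, and adjusted p = 0.0263 with an estimated correlation). Of 14 interferon response genes, 7 were higher when adjusted over the list alone (median 1.10, adjusted p = 2.13e-11, and adjusted p = 0.0482 with an estimated correlation). Epithelial adhesion genes were lower in 3 cases when adjusted over the list alone (median -2.41), Notch genes in 2 (-0.80), and B cell markers were higher in 3 (1.56) (adjusted p = 0.269 with an estimated correlation for each). The mean of the epithelial list was 7.39 ± 0.732 (SD, n = 3) in HrasKO and 9.81 ± 1.52 (SD, n = 8) in WT metastases. Hyperplastic epidermis was lower, with 1 gene past the threshold when adjusted over the list alone (-1.94, adjusted p = 0.235 with an estimated correlation). Cornified differentiation (-0.74) and hair follicle lists (-0.18) were lower, and endothelial (0.75) and T cell lists (1.22) higher (adjusted p = 0.375 with an estimated correlation for each). Skeletal muscle (-0.54, adjusted p = 0.704), adipocyte (1.30, adjusted p = 0.63) and lung lists (1.09, adjusted p = 0.706) were lost as well with an estimated correlation.

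By limma, 9 genes were higher and 20 lower in HrasKO SCC metastases. These arrays stood apart from their label: 5 of the 6 HrasKO arrays, in 3 of 3 mice, lay closest to spindle tumours, against 1 of the 18 WT arrays, in 1 of 8 mice (Fisher's exact test over mice, two-sided p = 0.0242, chosen after the profiles had been seen). Without them 1 HrasKO mouse remained, assumed to vary like the others. Moxd1 was then at 0.40, Pitx1 at 0.34, Tfap2a at 0.09, Stra6 at 0.13, Epha2 at 0.02 and Strip2 at -0.15, and the Ras-MAPK and interferon medians were 0.08 and -0.23. The count was 193 with individual arrays, 45 in batch 1 alone (32 higher, 13 lower), 53 with no batch covariate (27 and 26) and 1 with lymph node metastases alone. Leaving out 1 mouse gave counts from 0 (without 1383, 1984 or 2104) to 306 (without 1949).

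In spindle metastases (4 HrasKO and 3 WT mice), no gene passed by limma, with 394 at an unadjusted p under 0.05. Mast cell markers were lower in HrasKO mice, 2 of 7 when adjusted over the list alone (median -0.74, adjusted p = 3.74e-05, and adjusted p = 0.00471 with an estimated correlation). The proteases Mcpt4 and Cpa3 were at -2.71 (SE 0.658, adjusted p = 0.999) and -2.61. Epithelial (0.73, adjusted p = 0.737), skeletal muscle (0.13, 0.962) and lung lists (1.70, 0.494) were higher and lost with an estimated correlation. All lung arrays here were HrasKO, so site and genotype were partly bound for each list. Lrrc56 had a change of 1.28 and Nras of 0.10 (adjusted p = 0.999 each).

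Tumours of 1 mouse resembled each other more than tumours of different mice after centring within groups. The correlation of SCC metastases with the SCC carcinoma of their own mouse exceeded that with other mice by 0.225 (exact one-sided p = 0.003, adjusted p = 0.0061), with a same-mouse r of 0.196 ± 0.221 (SD, n = 8), and 5 of 8 mice were closest to their own. The excess was 0.215 for spindle metastases and carcinomas (exact one-sided p = 0.0091, adjusted p = 0.012), with 3 of 7 mice closest to their own. It was 0.104 for metastases and skin (permutation one-sided p = 0.0011, adjusted p = 0.0042, 3 of 15 mice closest to their own) and 0.112 for papillomas and skin (permutation one-sided p = 0.038, adjusted p = 0.038, 2 of 13 mice closest to their own). The papilloma and skin value was lost in batch 1 alone (0.0960, permutation one-sided p = 0.092) and with centring within genotype (0.0930, permutation one-sided p = 0.07).

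Across the 15 comparisons, 159 of 465 list tests were called at the preset correlation. Those that held with an estimated correlation were matrix protease, neutrophil and melanocyte in SCC carcinoma against papilloma, and cornified differentiation and hyperplastic epidermis in spindle against SCC carcinoma. In SCC metastases against carcinomas they were cornified differentiation, hyperplastic epidermis, matrix protease, B cell and plasma cell, and in spindle metastases against carcinomas interferon response and adipocyte. The Notch list held between spindle and SCC metastases, and the lung list between lung and lymph node. Between genotypes, cell cycle and Ras-MAPK targets held in papillomas, Ras-MAPK targets and interferon response in SCC metastases, and mast cell in spindle metastases. The median, the mean and the test had the same sign in all 159 calls. They differed in sign for 58 of the 306 lists not called, whose medians lay between -0.19 and 0.25. Of the 159 calls, 68 were kept in every alternative, and 44 were lost without the arrays that stood apart.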

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

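Tests of label exchange, stromal share, lymphoid RNA, host lymph node B cells and keratinocyte share in this part were chosen after the result was seen, and the epithelial covariate was chosen before.

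Of 101 groups of 4 to 10 mice tested for a mouse far from the rest, 16 held 1, and chance alone flags about 1 in 20 groups. In spindle carcinomas, mouse 1949 stood out in 5 lists. Its epithelial adhesion mean was 10.9 (nearest other mouse 7.60), its Notch mean 9.44 (8.15), its mesenchymal mean 9.42 (10.5), its Ras gene mean 8.91 (9.86) and its macrophage mean 8.41 (9.69). Also in spindle carcinomas, the hair follicle mean was 6.52 in mouse 1537 (5.28), the plasma cell mean 6.01 in mouse 2022 (5.46) and the Langerhans cell mean 7.98 in mouse 1984 (8.84). In SCC carcinomas, the Ras-MAPK mean was 9.01 in mouse 1456 (9.34), the interferon mean 5.57 in mouse 1984 (6.11) and the melanocyte mean 5.91 in mouse 1949 (4.79). Mouse 1508 had the highest liver mean of these, at 4.94 (4.4), and the highest kidney mean, at 4.88 (4.48). In spindle metastases, mouse 1537 had an epithelial mean of 7.25 (6.15) and a kidney mean of 4.74 (4.41), and mouse 1509 a Langerhans cell mean of 9.90 (9.17).

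The change from skin to papilloma differed between genotypes in 4 lists by a test of the difference itself at the preset correlation. The median difference was 1.08 for epithelial adhesion, -0.54 for cell cycle, -1.44 for adipocyte and -0.48 for endothelial markers (adjusted p = 0.792 with an estimated correlation for each). The change from carcinoma to metastasis differed between spindle and SCC histology in 10 lists by the same kind of test. The median difference was 1.80 for cornified differentiation and -0.58 for Ras genes (adjusted p = 0.382 with an estimated correlation for each), 0.71 for hyperplastic epidermis (adjusted p = 0.642) and 0.92 for adipocyte markers (adjusted p = 0.309). It was -0.33 for mesenchymal and 0.26 for cell cycle genes (adjusted p = 0.913 with an estimated correlation for each) and -0.70 for skeletal muscle (adjusted p = 0.604). For Ras-MAPK targets it was -0.67, for macrophage markers -0.75 and for spleen or erythroid markers 0.81 (adjusted p = 0.57 with an estimated correlation for each). When adjusted over the list alone, 5 hyperplastic epidermis, 4 cornified, 2 adipocyte and 1 of the Ras genes passed, and none in the other lists named in this paragraph.

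A first pattern was that 4 of the 27 papilloma arrays, from mice 1508, 1815 and 1984, lay closest to spindle arrays of other mice. Labels exchanged with a spindle array of the same mouse would need a partner out of place, and 0 such arrays were found, which argues against an exchange. A larger share of stromal and immune cells would raise 6 marker lists together. Of the 4 arrays, 1 had all 6 at or above the median of the 23 others. With so few arrays a stromal share stays open. Muscle, not among the 6, was present in those of 1815 and 1984 (means of 7.22 to 8.96). A single wrong label, an outside swap or a papilloma in progression stays open and was not tested.

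A second pattern was the set of 29 genes between HrasKO and WT SCC metastases. With the epithelial adhesion mean as a covariate, for lower epithelial content, the median change of these genes went from 1.64 (SE 0.252) to 1.42 (SE 0.261), so that 86.5% remained, but 0 of the 29 were still called by limma with that covariate. The bound set beforehand was met by less than the spread of the value, a requirement added after the value was seen, so lower epithelial content cannot be told apart from an effect of genotype. Lymphoid RNA of the host organ would raise lymphoid markers: the B cell list had a median of 1.56, while 0 of the 9 higher genes were in the T cell, B cell or plasma cell lists, and with 3 HrasKO mice it cannot be told apart either. The spindle-like profile of 5 of the 6 HrasKO arrays and the genotype itself stay open.

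A further pattern was that B cell genes were higher and cornified genes lower in SCC metastases than in SCC carcinomas. B cells of the host lymph node as the only source would leave lung metastases at the level of the carcinomas. In the 5 WT mice with an SCC carcinoma and a lung SCC metastasis, the B cell mean was higher in the lung in 5 of 5, by 1.17 on average (SD 0.511, range 0.28 to 1.52), which argues against that source alone. Without mouse 1949, whose lung array stood apart, it was 4 of 4, by 1.08 (SD 0.545). The lymph node mean was above the lung mean in 2 of the 3 of these mice with both, and in 3 of all 8 mice with both, of either genotype and histology (mean difference -1.02, SD 2.16), so lymph node B cells as a part of the source stay open. Fewer tumour keratinocytes per sample would lower all epithelial genes alike, and the epithelial adhesion median was 22.7% of the cornified median, which argues against it as the whole cause. B cells of either host organ, B cells drawn to the tumour and a loss of differentiation in the metastases stay open as hypotheses.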

How the results depend on the processing

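Alternatives with the arrays that stood apart left out, with the papilloma arrays with muscle transcripts left out and with a mouse correlation from fewer genes were chosen after the result was seen, and so was the fit without a mouse term where no correlation could be estimated. Of 300 alternative gene counts, 176 were within 1.5 times the reported count, 51 were higher and 73 lower. Of 9300 alternative list tests, 8642 kept their side of the threshold, 343 became called, 288 were lost and 27 turned. Of 20350 such named-gene values, 19077 kept it, 221 became called, 1046 were lost and 6 turned. Turns count called results only. Of 67 similarity values, 57 kept their call. Unless a smaller number of mice or arrays is named, the cause was not tested. In each of the 15 comparisons fewer lists were called with an estimated correlation: 0 for papilloma against skin, 3 for SCC carcinoma and 0 for spindle carcinoma against papilloma, 2 between the carcinomas, 5 and 2 for SCC and spindle metastases against carcinomas, 1 between the metastases, 1 for lung against lymph node, 0, 2, 0, 2 and 1 for HrasKO skin, papilloma, spindle carcinoma, SCC metastasis and spindle metastasis, and 0 for both differences of changes. On arrays, the signal over background limits genes at low levels, and the counts of 0 with limma leave changes of moderate size open.

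With individual arrays, which count tumours of 1 mouse as more than 1 value, the counts were 216 for SCC carcinoma against papilloma, 2140 for spindle against SCC carcinoma, 2462 for SCC and 22 for spindle metastasis against carcinoma, 1951 for spindle against SCC metastasis, 83 for lung against lymph node, 193 for HrasKO SCC metastasis, 34 for the genotype difference of changes and 98 for the histology difference. With no mouse term they were 0 for spindle against SCC metastasis and 28 for lung against lymph node. A fixed mouse block, which rests on fewer mice, gave 0 for spindle against SCC in carcinomas and in metastases. The filter on low values gave 372 for spindle against SCC metastasis and 0 for HrasKO papilloma, and the trended and robust variance gave 0 for spindle against SCC metastasis. Repeated quantile normalization gave 65 for SCC carcinoma against papilloma (12 higher, 53 lower), 1 for spindle metastasis against carcinoma and 103 for spindle against SCC metastasis.

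Batch 1 alone, with fewer mice, gave 0 for SCC carcinoma against papilloma, 2278 for spindle carcinoma against papilloma, 657 for spindle against SCC carcinoma, 202 for SCC metastasis against carcinoma, 0 for spindle against SCC metastasis, 0 for HrasKO skin and papilloma and 45 for HrasKO SCC metastasis (32 higher, 13 lower). The lung and lymph node comparison then had a skeletal muscle median of 0.063, and the HrasKO SCC metastasis test of skeletal muscle turned at a median of -0.12. With no batch covariate the counts were 2 for HrasKO papilloma and 53 for HrasKO SCC metastasis. With no genotype covariate the count was 611 for spindle against SCC metastasis, and with both genotypes 4297 for spindle against SCC carcinoma. Mice of a shared histology gave 18 for lung against lymph node. A mouse correlation from fewer genes gave 95 for spindle against SCC metastasis.

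Lymph node metastases alone gave 60 for SCC metastasis against carcinoma and 1 for HrasKO SCC metastasis. In spindle metastasis against carcinoma the mesenchymal median was then 0.14, the lung median 0.001 and the liver median -0.05. The lung medians of HrasKO SCC and spindle metastases were 0.03 and 0.011. The histology difference of changes had medians of 0.10 for mesenchymal, -0.35 for hyperplastic epidermis and -0.10 for spleen or erythroid. Leaving out RegCA carcinomas, which were mostly spindle, also removed the mice with no other spindle carcinoma. The counts were then 0 for spindle carcinoma against papilloma and 19 for the histology difference. HrasKO spindle carcinomas then had medians of -0.013 for hair follicle and -0.22 for endothelial markers, where the test turned.

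Without the arrays that stood apart the counts were 377 for SCC and 7912 for spindle carcinoma against papilloma, 3679 for spindle against SCC carcinoma, 459 for SCC and 1 for spindle metastasis against carcinoma, 24 for lung against lymph node and 1 for HrasKO SCC metastasis. With no mouse term either, they were 1484 for spindle against SCC metastasis and 3 for the histology difference. In HrasKO papillomas 1 gene was called, a different one and higher, and without the papilloma arrays with muscle transcripts the count was 2, both higher. Medians were -0.12 for cornified differentiation and -0.038 for epithelial adhesion there, and -0.039 for Ras-MAPK and 0.071 for T cell markers in lung against lymph node, where the test turned. In HrasKO SCC metastases the changes were 0.023 for Epha2, 0.40 for Moxd1, 0.34 for Pitx1, 0.13 for Stra6, 0.087 for Tfap2a and -0.15 for Strip2, and the medians 0.085 for Ras-MAPK, -0.23 for interferon, -1.40 for T cell, -1.40 for B cell and -1.41 for lung markers, where 1 HrasKO mouse remained.

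Leaving out 1 mouse gave 7278 to 8589 for papilloma against skin, always within 1.5 times. SCC carcinoma against papilloma ran from 0 (without 1383, 1456 or 2022) over 8 (2104), 15 (1949), 17 (1717) and 20 (1984) to 89 (1508). Spindle carcinoma against papilloma ran from 2105 (1383), 2221 (1509), 2278 (1664) and 2619 (1407) to 5785 (1815). Spindle against SCC carcinoma ran from 1 (1984), 3 (1508), 21 (1383), 189 (2022), 657 (1456), 705 (2104), 715 (1815) and 840 (1717) to 4056 (1949). SCC metastasis against carcinoma ran from 202 (1456), 337 (1984), 459 (1949), 531 (1717), 533 (1383), 537 (1508) and 553 (2022) to 892 (2104). Spindle metastasis against carcinoma ran from 0 to 1 (1949), and lung against lymph node from 0 to 17 (1949). Spindle against SCC metastasis ran from 0 (1383, 1407, 1456, 1616, 1664, 1717 or 1984) over 3 (2104), 5 (1815), 7 (2022), 21 (1508), 72 (1706), 137 (1537) and 148 (1949) to 412 (1509). HrasKO skin ran from 0 (1456, 1509, 1616 or 1664) to 2 (1949 or 2022). HrasKO papilloma was 0 without 1383, 1407, 1456, 1508, 1664, 1706, 1949, 1984 or 2104, 4 without 1815 and 33 without 1509. HrasKO spindle carcinoma ran from 0 to 1 (1537). HrasKO SCC metastasis ran from 0 (1383, 1984 or 2104) over 1 (1706), 2 (1616), 9 (2022), 16 (1717), 45 (1456 or 1664) and 133 (1508) to 306 (1949). HrasKO spindle metastasis and the genotype difference of changes stayed at 0 with limma. The histology difference ran from 0 over 2 (1383) to 11 (2022), with 3 in a refit without a mouse term. List medians whose test turned when 1 mouse was left out ran from -1.38 to 0.063 for skeletal muscle, from -0.57 to -0.038 for Ras-MAPK and from 0.071 to 1.31 for T cell markers in lung against lymph node (turned without 1456, 1616 and 1616), from -0.045 to 0.73 for hair follicle in HrasKO spindle carcinoma (1537), and from -0.90 to -0.12 for skeletal muscle in HrasKO SCC metastasis (1456 or 1664).

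The similarity of papillomas to skin was 0.13 with the most variable genes (permutation one-sided p = 0.053), 0.096 in batch 1 alone and 0.093 with centring within genotype, and lost its call in each. Leaving out 1 mouse gave 0.084 (1706) to 0.145 (1815), and the call was lost without 1407 (0.089), 1456 (0.09), 1508 (0.09), 1706 (0.084), 1949 (0.11) or 2104 (0.103). Spindle metastasis against carcinoma ran from 0.139 (1984, where the call was lost) to 0.298 (1949), SCC metastasis against carcinoma from 0.149 (1949) to 0.344 (1508), and metastasis against skin from 0.081 (1706) to 0.126 (1664).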

Other observations

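The exact tests of list levels per mouse, those of Lrrc56 and the test of the chromosome region around it in this part were chosen after the result was seen, and the regroupings were planned.

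Liver markers were present in the liver metastases, where the liver list had a median of 9.89 over 3 arrays. Lung metastases had lung marker means from 4.53 to 10.6, with a median of 9.26 over 10 arrays. In the kidney metastasis the kidney list was at 4.24, and the dorsal metastasis had an epithelial adhesion mean of 10.5. Of the 4 arrays of mixed histology, 2 carcinomas and the lung metastasis lay closest to spindle arrays (correlations of 0.961, 0.962 and 0.952), and the carcinoma of mouse 1706 lay closest to SCC arrays (0.960).

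Per mouse, the cell cycle mean of papillomas was 8.74 ± 0.434 (SD, n = 4) in HrasKO and 9.43 ± 0.241 (SD, n = 9) in WT mice, a difference of -0.69 (exact two-sided permutation p = 0.00699, adjusted p = 0.049 over 10 tests). Of the 4 HrasKO mice, 3 lay below all WT mice. Both lists were picked from 31 with the result known, so these tests, exact and two-sided, are no new evidence. Without the 6 papilloma arrays with muscle transcripts the difference was -0.30 (4 and 8 mice, permutation p = 0.164), with 1 HrasKO mouse below all WT mice. Of these, 2 were HrasKO arrays with low cell cycle means. The Ras-MAPK difference was -0.52 (permutation p = 0.00979, adjusted p = 0.049). Without those arrays it was -0.44 (permutation p = 0.00202, not adjusted), with 4 of 4 HrasKO mice below all WT mice. In SCC metastases it was -0.65 (permutation p = 0.0242, adjusted p = 0.0807), with 2 of 3 HrasKO mice below all WT mice. The other 7 tests had a p of at least 0.125.

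Lrrc56, the gene next to the targeted one in the RefSeq gene order, was higher in HrasKO mice in all 4 tissues, with no overlap of mouse means. The difference was 0.78 in skin, where the gene had been picked for its difference and no further test is given, and 1.5 in carcinomas and 1.19 in metastases of the same mice (6 and 9 mice, exact two-sided permutation p = 0.0002 each, the smallest these mice can give) and 0.95 in papillomas (4 and 9 mice, exact two-sided permutation p = 0.0014, the smallest they can give). A change of the chromosome region around the targeted gene rather than of Lrrc56 alone would move many neighbours. Of the 20 nearest measured genes, 2 had an unadjusted p under 0.05 by limma in skin (11% of all genes), 2 in papillomas (5.11%), 1 in spindle carcinomas (3.33%), 5 in SCC metastases (12.6%) and 1 in spindle metastases (2.1%). A regional change cannot be told apart from an effect of the knockout allele on Lrrc56 itself, since the count of 5 goes with it and 20 genes are few.

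Other groupings of the mice were fitted with limma to ask whether chance can be excluded. Of 100 groupings, only the real grouping gave as many genes for papilloma against skin (7993, highest other 1) and SCC carcinoma against papilloma (38, 1). The same held for spindle against SCC carcinoma (1419, 1), SCC metastasis against carcinoma (854, 0) and spindle against SCC metastasis (13, 2). Chance is unlikely there, but counts of 38, 1419 and 13 fell to 0 in some alternatives. For spindle carcinoma against papilloma 2 of 100 gave as many (4470, highest other 5285), so chance is unlikely but not excluded. The other grouping exchanged mice 1815 and 1949, which hold arrays that stood apart. Chance cannot be excluded for the genotype counts of skin (6 of 100 gave as many, 1, highest other 57), papilloma (8 of 100, 1, highest other 1579) and SCC metastasis (5 of 100, 29, highest other 90). Where the real count was 0, every grouping gives as many and decides nothing. This holds for HrasKO spindle carcinoma (100 of 100, highest other 22), HrasKO spindle metastasis (35 of 35, 457), the genotype difference of changes (100 of 100, 1674), spindle metastasis against carcinoma (64 of 64, 1), lung against lymph node (100 of 100, 42) and the histology difference (100 of 100, 1). The counts of 57, 1579, 457 and 1674 are maxima of up to 100 groupings, with no source tested. That of 1579 moved 1509, 1706, 1508 and 1815, the last 2 with spindle-like papillomas.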
